A study of Homo sapiens with 6 samples.

How the data were processed

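RNA was measured in MDA-MB-436, an established human breast tumour cell line, on Affymetrix arrays of 54675 probe sets. Of the 6 arrays, 3 are labelled as wild type cells and 3 as cells transfected with NF1-C2S. The series record writes the construct NF1-C2, a form of nuclear factor I-C (gene NFIC), and says that it was carried by an expression plasmid in a stable transfection. Its isoform, species and tag, and whether a clone or a pool of cells was profiled, are not given in the sources used here. Per the labels' protocols, the cells grew in RPMI medium with serum and insulin, total RNA was taken with Trizol, and the RNA was labelled with biotin. The groups and the replicate numbers were taken from the labels alone. The comparison cells are called wild type, and the labels name no cells that carry an empty plasmid. Nothing in the labels says that the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

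The authors deposited 1 table of log2 expression values with a column per array, and per the submitters' processing notes the values were made with RMA, which corrects background, normalizes arrays to a common distribution and summarizes the probes of each probe set. The version of that tool and the arrays that were normalized together are not given in the sources used here. RMA compresses differences near the dim end of the scale, so fold changes of genes that are close to background in a group are likely to be too small rather than too large. A fold is given as "at least" where the dimmer group's mean is under the median of all probe sets, 4.83. Deposited values ranged from 2.35 to 14.62 on the log2 scale, with array medians from 4.8 to 4.85. Most values are rounded to 2 decimals, while 6354 values of wild type replicate 3 carry more digits. Arrays have no read depth, and the number of arrays limits the precision. The median SD over probe sets was 0.110 among wild type arrays and 0.119 among transfected arrays.

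The 62 control probe sets were left out of the tests, which left 54613 probe sets. Genes were named through the annotation of the array platform. It gave 41091 probe sets 1 gene, 1801 several genes and 11721 none. Of the probe sets with 1 gene, 41037 matched a table of human genes of assembly GRCh38.p14 by gene identifier, and the other 54 kept the name of the platform annotation. That table was used only for names and for the order of genes along chromosomes. A gene was represented by the brightest probe set, by mean over the 6 arrays, among those that name only that gene, which gave 19775 genes. Members of the gene lists without such a probe set were not analysed here.

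The 2 groups were compared on the deposited log2 values with limma 3.58.1 in R 4.3.3 (linear model per gene and empirical Bayes moderation of the variance, two-sided), and p-values were adjusted by the Benjamini-Hochberg method over all 19775 genes, with an adjusted p under 0.05 as the threshold. The same fit over all 54613 probe sets gave the values of single probe sets. Fold changes are transfected minus wild type. A total of 23 gene lists (the nuclear factor I family, the forkhead box F and hedgehog genes, epithelial, mesenchymal, luminal and basal mammary genes, pathways, and markers of other cell types) were written before the data were examined, as were the rule for named genes and all alternatives except one. The 22 lists with at least 5 measured members were tested with camera from limma at a preset correlation of 0.01 between genes, which asks whether a list moved relative to the other genes, and their p-values were adjusted over those lists. Counts "adjusted over the list alone" use the Benjamini-Hochberg method within a list.

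By that rule the text names every nuclear factor I gene and FOXF1, the 12 largest rises and 12 largest falls past the threshold whose groups do not overlap, and up to 4 members of each list with the largest changes past the threshold, which made 101 genes. All 100 of these that passed the threshold had groups that do not overlap. Genes named outside the rule are said to be so. A gene in more than 1 list counts in each.

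Because the groups share replicate numbers, the arrays of 1 number were tested for shared deviations from their group means. Their correlations over probe sets were 0.398, 0.238 and 0.140 for replicates 1, 2 and 3, all above 0.1. Arrays of different numbers gave -0.277 to 0.142. The value of 0.142, for wild type replicate 2 with transfected replicate 3, is above that of the same-numbered pair 3. Whether the numbers of the labels pair the arrays therefore stays open. What a shared number stands for is not given in the sources used here. The planned test leaves the pairing out, and a fit with the replicate number as a block called 6665 genes in place of 6300.

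The alternatives were other normalizations (quantile, median centring, cyclic loess), array weights, a variance prior with trend and robust moderation, leaving out the dimmer 50% of probe sets, the mean of a gene's probe sets, leaving out probe sets whose names end in _x_at or _s_at (which can bind several transcripts), the replicate block, leaving out each array in turn, other list tests (camera with an estimated correlation, camera on ranks, fry), and, chosen after seeing the data, subtracting per array the median deviation of the 20 nearest genes. Gene order was examined over 19690 genes that have a place on chromosomes 1 to 22 or X, with 10000 shuffles of the order, and in 641 windows of 20 consecutive genes drawn from the 13074 genes whose mean reached the median of all probe sets, 4.83, in at least 1 group, with 1000 shuffles. The steps were tested on simulated data over 19775 genes with the means and spreads of these arrays and 200 changed genes. In that simulation limma recovered 40% of genes changed by 0.5 on the log2 scale, 84% of those changed by 1, 96% of those changed by 2 and 100% of those changed by 3, with 5 false calls among 165. The simulated noise was independent between genes, and 6300 genes passed on the real arrays, so these rates may not apply to them.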

Results

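Expression was measured on 6 arrays of the breast tumour line MDA-MB-436, 3 labelled wild type and 3 labelled NF1-C2S transfected, from cells that per the series record carry an NF1-C2 plasmid after stable transfection. MDA-MB-436 is a triple-negative line with mesenchymal features, and NF1-C2 is a form of the transcription factor nuclear factor I-C. The comparison addresses which genes differ in expression between such cells with and without the plasmid. Over all probe sets, the correlation between arrays was 0.996 within the wild type group, 0.992 to 0.997 within the transfected group and 0.971 to 0.976 between the groups. The first principal component separated the groups and held 76.8% of the variance. The 3' minus 5' signal differences of GAPDH and ACTB changed between the groups by 0.03 and 0.02 on the log2 scale. Both changes were less than the range within a group.

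The gene of the factor that the labels name, NFIC, was not higher on the arrays labelled transfected. Its brightest probe set, 226895_at, read 8.47 ± 0.06 on the log2 scale in the wild type arrays and 8.25 ± 0.04 in the transfected arrays (SD, n = 3 each), a fall by 0.22 (SE 0.07; limma adjusted p = 0.047) that missed the threshold with the replicate block (adjusted p = 0.0529), when any 1 array was left out and over all probe sets (adjusted p = 0.082). The other NFIC probe sets changed by -0.11, -0.51 and 0.22, with adjusted p-values of 0.568, 0.0536 and 0.466. Whether any of them lies in the part of the message that the plasmid carries is not given in the sources used here, so NFIC does not check the labels, and each direction reported rests on the labels. Among its paralogs, NFIA fell by 0.37 (adjusted p = 0.0112, but 0.192 for the mean of its probe sets and 0.0541 after the shift of neighbouring genes was subtracted), and NFIB, at 0.12, did not pass the test (adjusted p = 0.311).

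The probe sets of NFIX, a further paralog, went opposite ways. The brightest one fell from 9.41 ± 0.07 to 8.34 ± 0.04 (log2 change -1.07, SE 0.07, adjusted p = 3.92e-05), another fell by 0.64 (adjusted p = 0.00382), and a dimmer one read -0.46 (adjusted p = 0.0857). The remaining probe set, 229834_at, rose from 4.79 ± 0.38 to 11.53 ± 0.21, a log2 change of 6.75 (SE 0.20, limma adjusted p = 1.41e-06 over probe sets) or at least 107-fold. This was the rise of rank 2 among all 54613 probe sets, and it turned the mean over the NFIX probe sets to 1.15. When wild type replicate 2 or 3 was left out it became the brightest NFIX probe set, with a log2 change of 6.70 or 6.58.

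FOXF1, which encodes a forkhead transcription factor of mesenchyme, fell from 7.69 ± 0.16 to 4.17 ± 0.35, a decrease of at least 11.5-fold (log2 change -3.52, SE 0.18, limma adjusted p = 1.36e-05, n = 3 per group). Its relative FOXF2, named after its value was seen, also fell, by 0.61 (adjusted p = 0.000373). Of the 15 measured forkhead box F and hedgehog genes, 4 fell, 1 rose and 10 did not pass, with the same counts when adjusted over the list alone. The hedgehog effector GLI3 fell by 1.59 (log2 change -0.91 for the mean of its probe sets) and the co-receptor GAS1 also fell (log2 change -1.76), while the receptor PTCH1 rose by 0.64, or by 0.08 for the mean of its probe sets (adjusted p = 0.529). The fall of GAS1 was read by probe sets ending in _s_at, and the remaining one, at a level of 5.27, read 0.06. As a set the list did not pass (camera adjusted p = 0.443), and its median was 0.07 while its mean was -0.42.

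**Figure D1:**
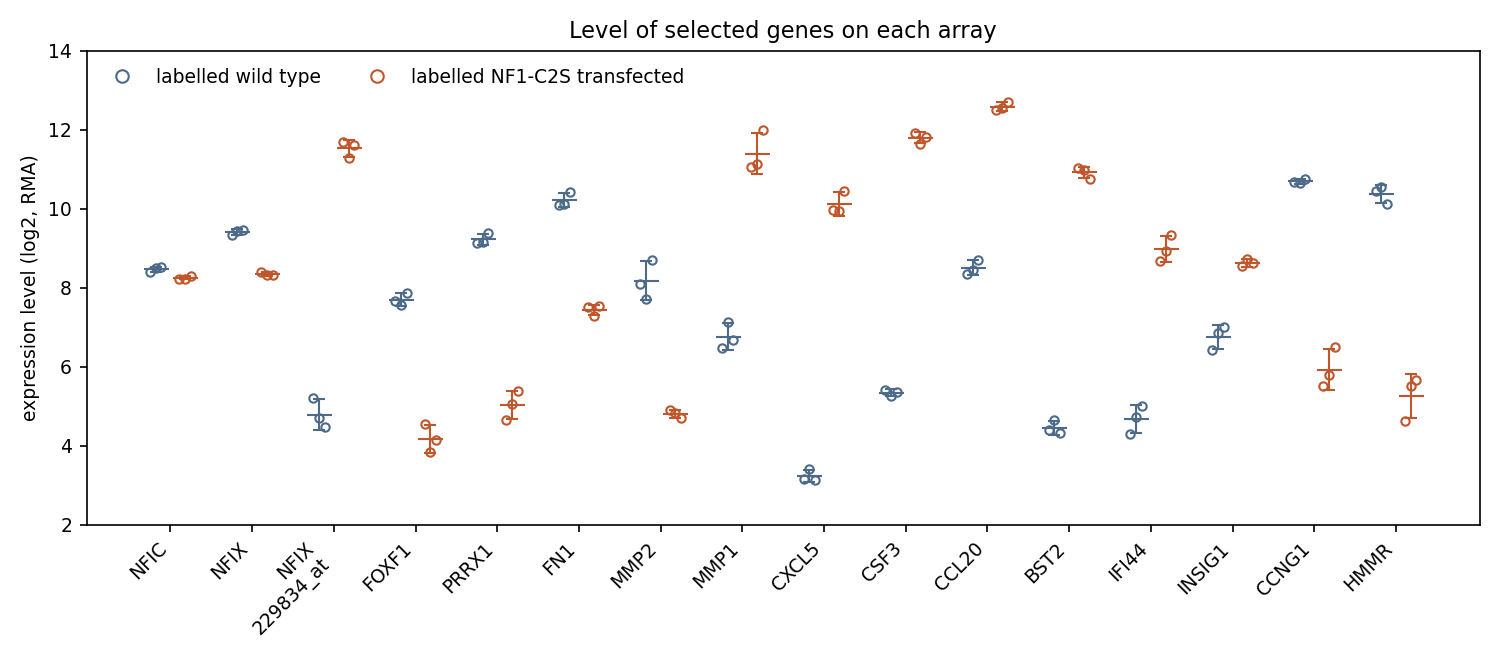
Log2 expression level (RMA) of selected genes on each array, with circles for single arrays, a horizontal mark for the mean and bars for the SD of 3 arrays. NFIX appears with its brightest probe set and again with 229834_at, which read 4.79 in the wild type and 11.53 in the transfected group, and the FOXF1 values lie near 7.69 and 4.17.

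Expression differed broadly. Of 19775 genes, 6300 passed the threshold (31.9%), 2961 higher and 3339 lower on the arrays labelled transfected, and 1327 of them differed by at least 2-fold, 568 higher and 759 lower. In 6289 of the 6300 genes the groups did not overlap, as was so for 43.0% of all genes tested, where 10% is the share given by chance for 3 arrays against 3. The largest measured rises were those of the neutrophil chemokine CXCL5 (3.23 ± 0.15, which is near background, to 10.12 ± 0.29, at least 119-fold, limma adjusted p = 9.29e-07), the interferon-induced membrane protein BST2 (4.45 ± 0.17 to 10.92 ± 0.14, at least 88.4-fold, 5.87e-07) and the granulocyte growth factor CSF3 (5.34 ± 0.09 to 11.79 ± 0.14, 87.4-fold, 2.98e-07). G0S2, an inhibitor of triglyceride lipase, rose by 6.01 and the cytokine IL24 by 5.97. On the only CXCL5 probe set that does not end in _x_at or _s_at, which was near background, the rise was 0.51 (adjusted p = 0.0354), and on that of IFI44 it was 1.503. AFAP1-AS1, PLTP, the collagenase MMP1, ZNF711, VNN1, IFI44 and ARMCX2 followed with rises from 5.13 down to 4.19.

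The steroid-metabolizing enzyme AKR1C3 had the largest measured fall, from 10.15 ± 0.30 to 3.78 ± 0.03 (at least 82.7-fold, limma adjusted p = 9.29e-07). CBFB, the partner of the RUNX transcription factors, fell from 9.44 ± 0.03 to 3.50 ± 0.24 (at least 61.4-fold), and NUDCD2 from 9.99 ± 0.05 to 4.17 ± 0.25 (at least 56.5-fold), on probe sets ending in _s_at beside a dim one that read -0.15. Further falls were those of the urea transporter SLC14A1 (log2 change -5.40), the basement membrane protein NID2 (-5.14), the hyaluronan receptor HMMR (-5.12), the growth factor binding protein IGFBP3 (-4.96), the tryptophan-pathway enzyme KYNU (-4.91), the cytokine IL18 (-4.89), cyclin G1 (CCNG1, -4.76), MAT2B (-4.74, but -0.57 on its dim probe set that does not end in _s_at) and S100P (-4.73). Most of these transcripts lay near the dim end of the scale in the transfected arrays, where folds are compressed, so their order also reflects the level in the wild type arrays.

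Cytokine and chemokine genes of the NF-kappaB list rose together. Of 38 measured members 26 rose, 5 fell and 7 did not pass (27 and 5 adjusted over the list alone), with a median log2 change of 0.90 (camera adjusted p = 1.95e-08; adjusted p = 0.232 with an estimated correlation). CCL20, a chemokine for memory T cells and dendritic cells, rose from 8.50 ± 0.19 to 12.59 ± 0.11, a 17.0-fold change, beside CXCL5 and CSF3. Cytokines named after their values were seen rose from levels that were already high: LIF by 2.75, IL1B by 2.38 and CXCL8 by 1.67. The members that fell included IL18, an inflammasome-processed cytokine, and the chemokine CXCL6 (log2 change -2.42), also named after its value was seen.

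Interferon-stimulated genes split. Of 45 measured, 20 rose, 7 fell and 18 did not pass (21 and 7 adjusted over the list alone), and the list shifted upward (median 0.11, mean 0.70, camera adjusted p = 0.00167; adjusted p = 0.491 with an estimated correlation). BST2 and IFI44 led, and the exonuclease ISG20 rose by 2.67 and IFIT3, an antiviral RNA-response protein, by 2.57. Classical members, named after their values were seen, differed. MX1, OAS1 and IFI27 read -0.21, 0.07 and 0.06 and did not pass, while OASL, RSAD2, IFIT1 and IFIT2 rose by 2.42, 2.34, 2.26 and 2.08. Among 26 antigen presentation genes, 7 rose, 2 fell and 17 did not pass, also when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.12, and 0.034 without wild type replicate 3). The lipid-presenting CD1D rose by 1.18 and the immunoproteasome subunit PSMB9 by 1.01. HLA-DMA, which loads peptides on class II molecules, fell by 0.81, and NLRC5, the class I transactivator, fell by 0.46, a call that ended when wild type replicate 2 or 3 or transfected replicate 3 was left out (adjusted p = 0.0559, 0.0797 and 0.0581).

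Mesenchymal genes shifted down as a list. Of 38 measured, 16 fell, 4 rose and 18 did not pass (18 and 4 adjusted over the list alone), with a median of -0.17 and a mean of -0.60 (camera adjusted p = 0.00047; adjusted p = 0.236 with an estimated correlation). The gelatinase MMP2 fell by 3.37 from 8.18 ± 0.50 (log2 change -1.11 for the mean of its probe sets, of which the other 2 are dim), fibrillin FBN1 from 9.51 ± 0.10 to 6.25 ± 0.18 (9.61-fold, or a log2 change of -1.91 without probe sets ending in _s_at), fibronectin FN1 from 10.21 ± 0.18 to 7.44 ± 0.13 (6.84-fold), and the crosslinking enzyme LOX fell by 2.42 (-1.57 for the mean). FN1 was read by probe sets ending in _x_at or _s_at, and without them the brightest remaining one, near background, read 0.02. Vimentin (VIM), named after its value was seen, fell by 0.53 from a level of 13.54. Of 21 transcription factors of epithelial-mesenchymal transition, 10 fell, 3 rose and 8 did not pass (10 and 4 adjusted over the list alone; median -0.40; camera adjusted p = 0.0423; adjusted p = 0.569 with an estimated correlation, and 0.0661 with the replicate block). The call of that list also ended without wild type replicate 3 or transfected replicate 2 (adjusted p = 0.0991 and 0.0644) and after the shift of neighbouring genes was subtracted (0.0518). Beside FOXF1, the homeobox gene PRRX1 fell from 9.23 ± 0.14 to 5.03 ± 0.36 (18.3-fold), and FOXC2 (-1.48, or -0.86 for the mean of its probe sets) and TWIST2 (-1.37, or -0.81 after the neighbours' shift was subtracted) fell. SNAI1 and SNAI2, named after their values were seen, read 0.12 and 0.10 (adjusted p = 0.589 and 0.746).

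Epithelial junction and identity genes went both ways. Of 40 measured, 8 rose, 8 fell and 24 did not pass (9 and 9 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.912, upward, with a median of -0.0018 and a mean of -0.10). The epithelial transcription factor ELF3 rose by 1.55 (0.86 without probe sets ending in _s_at) and tricellulin, MARVELD2, by 1.52 (0.95 for the mean of its probe sets). The surface glycoprotein CD24 fell from 11.55 ± 0.05 to 7.06 ± 0.37 (22.5-fold, limma adjusted p = 4.91e-06) and desmoplakin, DSP, fell by 1.36. All 6 CD24 probe sets fell past the threshold, and all end in _x_at or _s_at. E-cadherin (CDH1), named after its value was seen, lay near background at 3.42 and 3.44 (adjusted p = 0.894).

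Integrins, laminins and matrix proteases shifted down as a list of 58, with 24 lower, 9 higher and 25 not past the test, also when adjusted over the list alone (median -0.08, camera adjusted p = 0.0423; adjusted p = 0.362 with an estimated correlation, 0.057 without transfected replicate 3, and 0.0695 after the shift of neighbouring genes was subtracted). Nidogen-2 (NID2) and the hemidesmosome integrin ITGB4 fell, ITGB4 from 8.69 ± 0.47 to 5.10 ± 0.59. The matrix metalloproteases MMP1 and MMP3 rose by 4.63 and 3.99, MMP3 from 3.92 ± 0.35 to 7.91 ± 0.86. Of 21 basal mammary genes, 8 fell, 2 rose and 11 did not pass, also when adjusted over the list alone (median -0.19, camera adjusted p = 0.00624; adjusted p = 0.15 with an estimated correlation). They included ITGB4, the oxytocin receptor OXTR (log2 change -2.68), caveolin-2 (CAV2, -2.08, or -1.33 for the mean of its probe sets) and stratifin (SFN, -1.84). The call of ITGB4 was lost without probe sets ending in _x_at or _s_at, where a dim one read -0.09 (adjusted p = 0.87). Of 25 luminal mammary and prolactin pathway genes, 4 fell and 2 rose, also when adjusted over the list alone, and 19 did not pass (median 0.0054, mean -0.11, camera adjusted p = 0.801). Keratin KRT18 (log2 change -0.93), the luminal factor GATA3 (-1.33) and the cytokine-signalling inhibitor SOCS2 (-1.05) fell, and XBP1 rose by 0.38. GATA3 read -0.30 (adjusted p = 0.099) on the brightest probe set that does not end in _x_at or _s_at.

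TGF-beta and BMP genes shifted down: 16 of 37 fell, 10 rose and 11 did not pass (18 and 10 adjusted over the list alone; median -0.20; camera adjusted p = 0.0423; adjusted p = 0.254 with an estimated correlation, and 0.0805 or 0.0564 without wild type replicate 2 or 3). The activin subunit INHBA fell from 9.33 ± 0.04 to 5.39 ± 0.34 (15.3-fold), the TGF-beta-induced PMEPA1 from 10.17 ± 0.13 to 6.44 ± 0.07 (13.3-fold) and thrombospondin THBS1 fell by 2.61, although THBS1 read -0.09 without probe sets ending in _x_at or _s_at (adjusted p = 0.654). The BMP antagonist GREM1 rose from 7.46 ± 0.11 to 10.16 ± 0.34. In the Wnt and Notch list of 41, 16 fell, 4 rose and 21 did not pass (19 and 4 adjusted over the list alone; median -0.18; camera adjusted p = 0.0128; adjusted p = 0.15 with an estimated correlation). The members with the largest falls included Wnt antagonists, SFRP1 (log2 change -2.83) and DKK1 (-2.24), beside the ligand WNT5B (-2.36) and the Notch ligand JAG1 (-1.48). For the mean of their probe sets SFRP1, WNT5B and JAG1 read -1.75, -0.91 and -0.75.

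Cell cycle genes went both ways, and the list did not pass. Of 56 measured, 16 rose, 15 fell and 25 did not pass (19 and 15 adjusted over the list alone; camera adjusted p = 0.362). After the shift of neighbouring genes was subtracted, 13 were higher and 7 lower. Cyclin B2 (CCNB2) rose by 1.46 (0.53 for the mean of its probe sets, and 0.91 after that subtraction), the kinesin KIF23 by 0.85 and CHAF1A, a chromatin assembly subunit, by 0.78, against the fall of HMMR. CHAF1A read -0.12 on its only probe set that does not end in _x_at or _s_at, which was near background. Of 28 p53 targets and CDK inhibitors, 9 fell, 7 rose and 12 did not pass (9 and 8 adjusted over the list alone; median 0.01, mean -0.30, camera adjusted p = 0.912). CCNG1 and the death receptor FAS fell, FAS from 8.32 ± 0.06 to 4.21 ± 0.28 (at least 17.2-fold) on each of 4 probe sets past the threshold, all ending in _x_at or _s_at, while the fifth, near background, read 0.05. The CDK inhibitors CDKN1A and CDKN1C fell too (log2 changes -1.26 and -1.16).

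Sterol synthesis genes rose: 14 of 20 were higher, 1 lower and 5 not past the test, also when adjusted over the list alone (median 0.41, camera adjusted p = 6.1e-05; adjusted p = 0.15 with an estimated correlation). INSIG1, a sterol sensor partner, rose by 1.88, the demethylase MSMO1 by 1.08, the sterol carrier STARD4 by 0.92 and the synthase HMGCS1 by 0.84. Of 33 genes of unfolded protein and amino acid stress, 17 rose, 7 fell and 9 did not pass (19 and 7 adjusted over the list alone; median 0.38; camera adjusted p = 0.0129; adjusted p = 0.405 with an estimated correlation). DDIT4, an inhibitor of mTORC1, rose by 2.04 and the chaperone DNAJB9 by 1.16, while the amino acid transporter SLC7A5 (-1.83) and the stress protein NUPR1 (-1.37) fell. Among 34 hypoxia and glycolysis genes, 15 rose, 8 fell and 11 did not pass (15 and 9 adjusted over the list alone; median 0.0037, camera adjusted p = 0.136, and 0.000961 without probe sets ending in _x_at or _s_at). The glycolytic enzyme ALDOC rose from 4.83 ± 0.30 to 8.04 ± 0.22 (at least 9.29-fold), and the mitophagy receptors BNIP3L and BNIP3 rose 3.05-fold and 2.83-fold, while LOX fell.

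Oxidative phosphorylation genes fell by small amounts: 24 of 46 were lower, 8 higher and 14 not past the test (26 and 8 adjusted over the list alone; median -0.23; camera adjusted p = 0.00574; adjusted p = 0.15 with an estimated correlation), and 16 were lower and 4 higher after the shift of neighbouring genes was subtracted. NDUFA10, a complex I subunit, fell by 1.43 and UQCRC1, of complex III, also fell (-1.13, or -0.66 after that subtraction), and COX7C and NDUFC1 rose by 0.84 and 0.76. For the mean of their probe sets NDUFA10 and NDUFC1 read -0.45 and 0.30. Of 36 ribosomal protein genes, 7 fell, 2 rose and 27 did not pass, also when adjusted over the list alone (camera adjusted p = 0.451). RPLP1 rose by 0.57, a call lost without probe sets ending in _x_at or _s_at (adjusted p = 0.915), as was that of RPL14 (0.144). RPS7 rose by 0.38, and RPL14 and RPL30 fell (-0.37 and -0.34). After the shift of neighbouring genes was subtracted, an alternative chosen after seeing the data, 3 ribosomal protein genes were higher and 1 lower, RPL30 was instead higher by 0.30 and the calls of RPS7 and RPL14 ended (adjusted p = 0.329 and 0.0721).

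**Figure D2:**
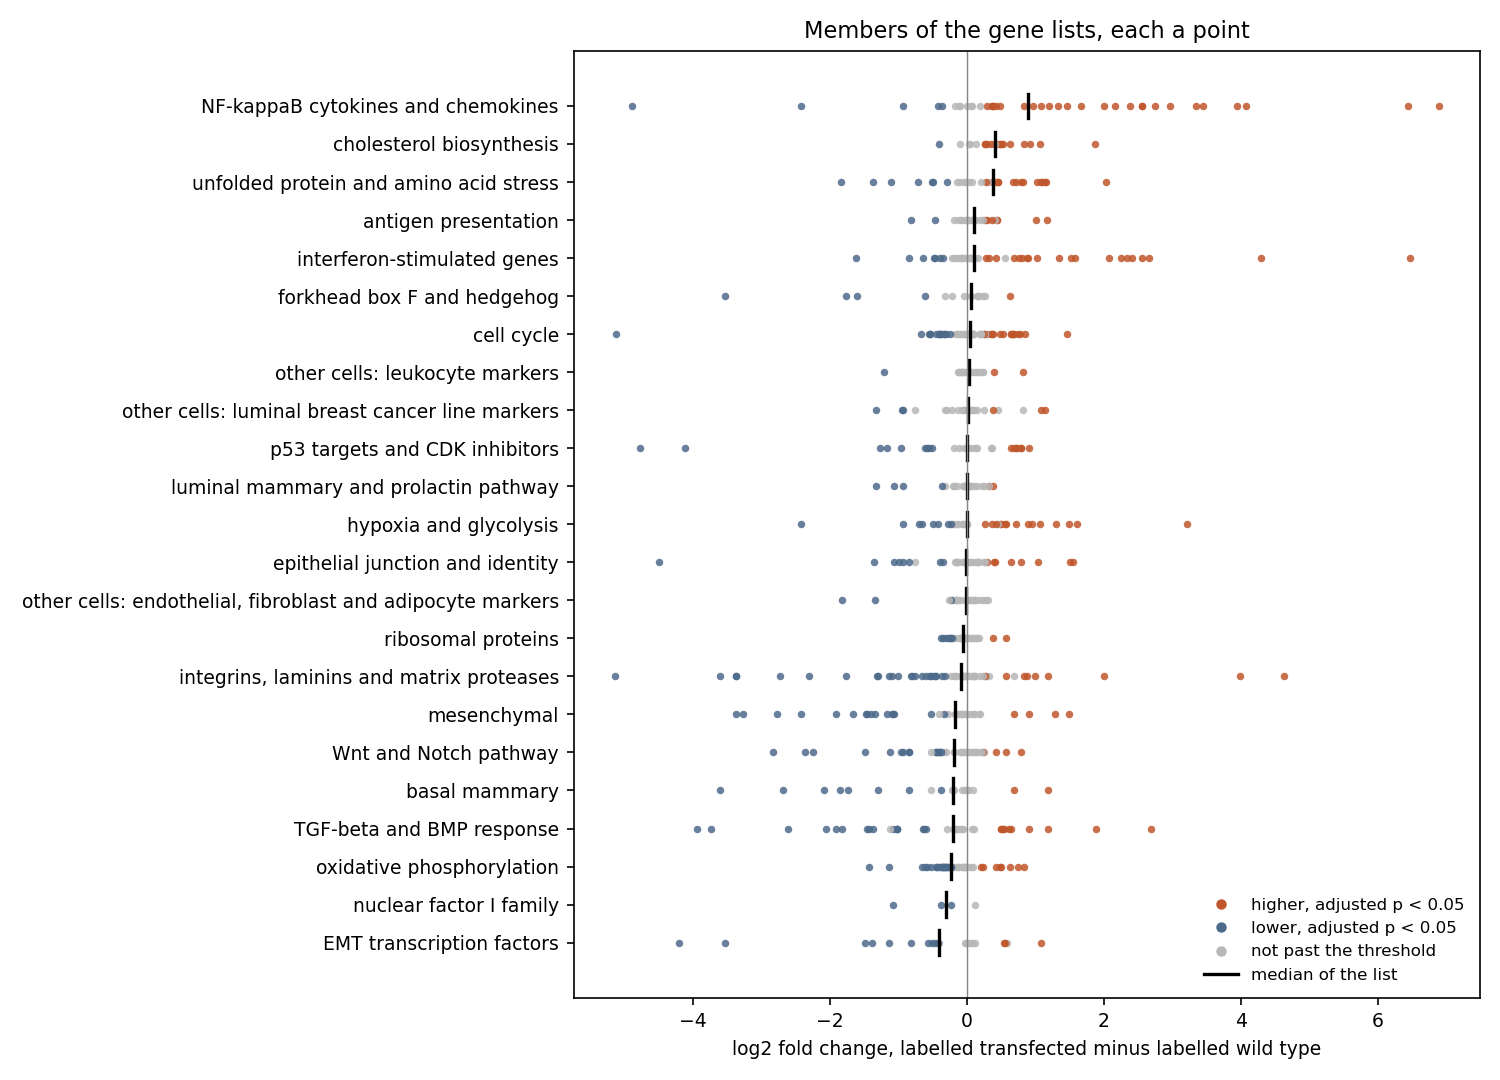
Log2 fold change (transfected minus wild type) of each measured member of the 23 gene lists, with lists in rows in the order of their medians, black bars for the medians and colours for members past an adjusted p of 0.05. The NF-kappaB list lies at a median of 0.90, while the transcription factors of epithelial-mesenchymal transition lie at -0.40.

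None of the 3 lists of other cell types passed the list test. Of 23 leukocyte markers, 2 rose, 1 fell and 20 did not pass (1 and 1 adjusted over the list alone; camera adjusted p = 0.612): CD14 rose by 0.83, CORO1A by 0.41 and ITGAM fell by 1.21. The call of CORO1A ended when wild type replicate 2 or 3 or transfected replicate 1 or 2 was left out (adjusted p = 0.0591 to 0.0986), that of ITGAM without probe sets ending in _x_at or _s_at (adjusted p = 0.718). Of 27 endothelial, fibroblast and adipocyte markers, 3 fell and 24 did not pass (2 fell adjusted over the list alone; camera adjusted p = 0.612). These were PPARG (log2 change -1.82), the fibroblast protease FAP (-1.33) and CSPG4 (-0.23), a call that ended with the replicate block (adjusted p = 0.0566) and when any 1 array except wild type replicate 2 was left out (0.0765 to 0.111). Of 25 markers of luminal breast cancer lines, 3 rose, 3 fell and 19 did not pass, also when adjusted over the list alone (median 0.02, mean -0.01, camera adjusted p = 0.919): STC2 and NAT1 rose by 1.14 and 1.09, and MLPH fell by 0.94 (log2 change -0.54 after the neighbours' shift was subtracted) beside GATA3 and KRT18.

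Genes that lie next to each other on a chromosome tended to change together. Over 19690 genes, the fold changes of neighbours correlated at 0.177, against at most 0.0338 in 10000 shuffles of gene order (a correlation across genes, which are not independent replicates). Of 641 windows of 20 neighbouring genes, 7 were higher and 8 lower than any window in 1000 shuffles. In the window from TCF12 to VPS13C on chromosome 15, 17 of 20 genes rose and none fell past the threshold (median 1.12), and in the window from MRPL44 to ITM2C on chromosome 2, 17 fell and 1 rose (median -1.17). Shifts also ran through longer stretches, picked here after their values were seen. On chromosome 3, every window from TRNT1 to MANF had a median between -0.82 and -0.33. Farther along, the windows from CCDC66 to CPOX had medians of 0.68, 0.81 and 0.64. On chromosome 22, by contrast, window medians stayed between -0.17 and 0.08. CCNG1, NUDCD2, HMMR and MAT2B, 4 of the 12 largest falls, were consecutive measured genes on chromosome 5 among the brighter genes.

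**Figure D3:**
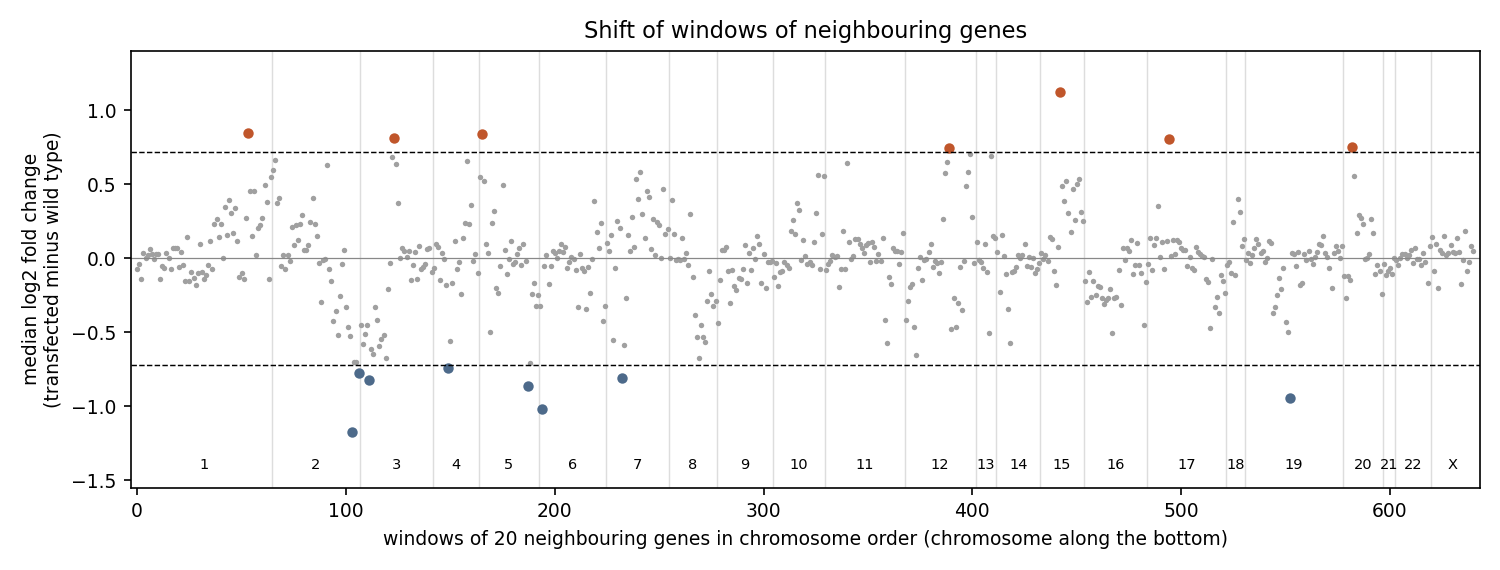
Median log2 fold change (transfected minus wild type) of 641 windows of 20 neighbouring genes in chromosome order, with grey lines between chromosomes. The dashed lines mark 0.72, the largest absolute median in 1000 shuffles of gene order, and the 15 coloured windows beyond them are 7 higher and 8 lower.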

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

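The tests of neighbouring genes as the whole cause of the count, of a luminal line as most of a group, of related neighbouring genes, of a wave of replicate size and of the NFIC and NFIX probe sets were chosen after the results were seen. Data outside the gene-level comparison also held signal: of 13522 probe sets that name no gene or several genes, 1600 (11.8%) passed an adjusted p of 0.05 in limma, 832 higher and 768 lower. The probe set 205114_s_at, which names 3 chemokine genes (CCL3, CCL3L1 and CCL3L3), rose by 5.34, and 204614_at, which names none, rose by 4.90 to a level of 12.05. The probe sets 215125_s_at and 221305_s_at, which name 9 and 5 genes of the UGT1A locus, changed by -5.93 and -5.67. These were chosen as the 2 largest rises and 2 largest falls among such probe sets.

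Of the 19775 genes tested, 6300 changed. Of the 10 splits of the 6 arrays into 3 and 3, only 1, the real one, gave as many. The other 9, among them 3 that also part every numbered pair, gave at most 0 genes in limma (149 to 837 at an unadjusted p under 0.05, against 7786), and 10 splits are too few for a share under 0.05. Each of those 9 mixes the 2 groups, whose difference then adds to the spread, so low counts there follow from any large difference. The normalization that moved the count most gave 6016 genes. RMA had already normalized the arrays to a common distribution, so this cannot decide on scaling. The tables argue against a single deviating array (5264 genes at the largest move). They also argue against RNA integrity, as the 3' minus 5' difference of ACTB changed by 0.0233 between the groups. Against a luminal line as most of 1 group, 8% of its markers differed by at least 2-fold in the commoner direction. CDH1 also lay near background in both groups, at 3.42 and 3.44. When the shift of the 20 nearest genes was subtracted, 4880 of the 6300 genes kept their call and direction (6155 called in all). This lowered the correlation of neighbouring genes from 0.177 to 0.0462. Most calls therefore outlasted the subtraction of the median shift of the 20 nearest genes. The subtraction cannot decide on copy number as the whole cause. It misses shifts of fewer genes, and 0.0462 is still above the highest value in shuffles, 0.0338. The 20 nearest genes were also taken at any level, and dim genes can hide part of a shift. Among the 13074 brighter genes, neighbours correlated at 0.236. What stays open is an effect of NF1-C2, which was not tested, and differences that a stably transfected population may carry apart from the plasmid. Copy number as part or all of the cause also stays open, as it could give the correlation of 0.177. So does a small share of luminal cells, about which markers that go both ways decide nothing (camera adjusted p = 0.919). No test addressed another line that is not luminal.

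Neighbouring genes moved together, a pattern that may reflect copy number differing between the cell populations. In windows chosen by every other gene, the genes not used to choose them shifted by 0.616 in the same direction, against at most 0.11 in shuffles. Related genes of like name side by side are not the main source, since the correlation was 0.169 without neighbours whose symbols share their first 3 letters. Neighbours of unlike name that share regulation were kept, so shared regulation stays open. A technical wave along the genome met the condition set for it before, because the difference of 2 replicates reached a neighbour correlation of 0.0987, over 50% of that between groups. A correlation leaves out size, however: a wave of that size could give 4.35% of the neighbour covariance between the groups. A wave of replicate size is therefore unlikely to be the whole cause. Replicates do not bound a wave that arose between the groups, so such a wave stays open. Copy number, which was not measured, stays open too.

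NFIC was not higher in the transfected arrays although the labels name a form of its product as transfected. The level of its brightest probe set, 8.36, lies far from both ends of the scale, which argues against a floor or ceiling. None of the 4 NFIC probe sets was higher past the threshold (0 in limma, and 0 at an unadjusted p under 0.05), and a message whose transfected part lies outside them cannot be told apart from a low expression of the plasmid without the probe positions. A candidate explanation of the NFIX probe set 229834_at, which rose by 6.75 while 2 other NFIX probe sets fell, is that it reads sequence of the plasmid, but a change in the NFIX transcript or another target would look the same here, and none was tested.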

How the results depend on the processing

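All alternatives were planned except the subtraction of the neighbours' shift, chosen after seeing the data. The 6300 changed genes became 4620 (without probe sets ending in _x_at or _s_at) to 6847 (trend and robust), 5264 to 6057 when 1 array was left out, and those changed at least 2-fold 918 to 1359. With median centring 5980 of the 6300 kept their call and direction, with the replicate block 6087 and after neighbour centring 4880. FOXF1 stayed past the threshold under each alternative. NFIC kept its direction and lost its call at -0.22 (median centring, adjusted p = 0.082; the replicate block, 0.0529; without _x_at and _s_at, 0.0707), at -0.16 for the mean of probe sets (0.334), at -0.24 after neighbour centring (0.0748) and at -0.26 to -0.20 when 1 array was left out, for which the cause was not tested. The block otherwise ended only the calls of CSPG4 and the list of transcription factors of epithelial-mesenchymal transition among named genes and lists. Reversed values came from other probe sets: the log2 fold change of NFIX was 1.15 for their mean and ran from -1.11 to 6.70 when 1 array was left out, and, without _x_at and _s_at, CHAF1A was at -0.12, GAS1 at 0.057, FN1 at 0.017 and FAS at 0.05. Those of CHAF1A, FN1 and FAS were dim (at most 4.05), while that of GAS1, at 5.27, was above the median of 4.83, and the cause was not tested. Named genes with no other probe set could not be tested without _x_at and _s_at, among them CD24, CBFB, CCNG1, G0S2, PLTP and KRT18. After neighbour centring 6155 genes were called, RPL30 turned to 0.30, and NFIA (adjusted p = 0.0541), RPS7 (0.329), RPL14 (0.0721) and the lists of epithelial-mesenchymal transcription factors (0.0518) and integrins (0.0695) lost their calls. Among named genes that kept their call, the log2 change shrank by over 1.5 times for 22 with the mean of probe sets (most of all NDUFA10, to -0.45, and MMP2, to -1.11), 5 without _x_at and _s_at (CXCL5, IFI44, ELF3, FBN1 and MAT2B) and 4 after neighbour centring (CCNB2, MLPH, TWIST2 and UQCRC1). It grew by over 1.5 times for CSPG4 with the mean of probe sets (to -0.41). After neighbour centring it grew as much for CSPG4 (to -0.50) and CORO1A (to 0.66). Of 22 lists 11 passed (4 higher, 7 lower). With an estimated correlation 0 passed, 0 higher and 0 lower (4 at an unadjusted p under 0.05), and the cause was not tested. The lists of epithelial-mesenchymal transcription factors, TGF-beta and BMP genes, and integrins were the least stable: they lost their calls without _x_at and _s_at (adjusted p = 0.142, 0.154 and 0.106) and on ranks (0.116, 0.0728 and 0.0991), the transcription factors also with the mean of probe sets (0.0613), and the transcription factors and TGF-beta and BMP genes without the dimmer 50% of probe sets (0.0809 and 0.102). On ranks 4 lower lists passed, without _x_at and _s_at 4, and with fry, which does not compare a list with other genes, 17 (11 lower). Near background RMA compresses differences, so changes that start or end there are likely to be read too small, although some dim probe sets passed, such as that of CXCL5 that rose by 0.51 without _x_at and _s_at.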

Other observations

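Members of other gene families, all named after their values were seen and tested as no list, also changed. The neighbouring aldo-keto reductases AKR1C1 and AKR1C2 fell with AKR1C3, by smaller amounts (AKR1C1 from 11.86 to 9.44, limma adjusted p = 3.26e-05; AKR1C2 from 10.89 to 8.19, adjusted p = 1.02e-05), and these genes are similar enough in sequence that their probe sets can share transcripts. Of the armadillo-repeat genes of the X chromosome, ARMCX4 rose from 3.73 to 7.62 (adjusted p = 9.29e-07) and ARMCX1 from 9.61 to 11.12 (adjusted p = 4.24e-05) beside ARMCX2, while ARMCX3, ARMCX5 and ARMCX6 read 0.03, 0.05 and -0.04 (adjusted p = 0.868, 0.806 and 0.78). BEX1, BEX2, BEX4 and BEX5 rose by 1.83 to 2.45 on the log2 scale, and BEX3 read 0.20 (adjusted p = 0.0831). AKR1C4, near background, read -0.13 (adjusted p = 0.446). The calls and directions of these 3 families were the same under each other normalization of the deposited values, which RMA had already normalized. The immune checkpoint ligand CD274, also named after its value was seen, rose by 4.17. Unlike CCNG1, CBFB fell without its neighbours: CES4A and PHAF1, named outside the rule for their place, read 0.03 and 0.08. They are the measured genes on either side among the brighter genes.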
